A study of Mus musculus with 14 samples.

How the data were processed

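RNA from mouse ascending aorta was extracted with Trizol and reverse-transcribed with SuperScript II, per the labels' protocols. The labels put the 14 libraries into 4 groups, and no library or column was left out. The deposited gene table holds 32289 genes, and that of transcripts holds 94714, each with an FPKM and an estimated count per library. Reads were aligned with HISAT2 2.2.1 and assembled with StringTie 2.1.6 on mm10, per the submitters' processing notes. The annotation release, the read filters and the strand setting are not given in the sources used here, so antisense and overlapping genes and close paralogs are uncertain. The deposited FPKM are the authors' fragments per kilobase of transcript, scaled to library size, for each gene or transcript. The deposited estimated counts are whole numbers that fit FPKM times length, rounded up, for 99.88% of low transcript values (tolerance 0.02), and a gene's count equals the sum over its transcripts for 99.995% of values. Gene identifiers matched GENCODE vM21 for 99.72% of genes, and 90.6% had the same coordinates. Coordinates are those of the deposited gene table, on mm10. An estimated count is not a count of reads assigned whole, so edgeR's model of counting error is an approximation here.

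Total counts were 49027885 to 72584877 per library. Replicates were compared in 18 pairs within groups. All differed by more than sampling noise, with a chi-square per degree of freedom of 41.5 or more, and log2 CPM correlations ran from 0.934 to 0.988, so each library counted as 1 sample.

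Before the data were examined, the groups, 32 gene lists (521 genes), the rule for named genes, the tests and most alternatives were fixed. The test written then was limma on log2(FPKM + 1), with edgeR quasi-likelihood in its place if the tables held counts. They did, so edgeR 4.0.16 in R 4.3.3 (TMM normalisation, 1 fit over all 14 libraries, Benjamini-Hochberg adjustment, threshold 0.05) is the main test. Genes with an FPKM of 1 or more in at least 3 libraries were tested, 13294 in all, which hold at least 98.84% of the counts of each library. The 6 comparisons are each fed group vs. PBS, each inhibitor vs. BAPN, and the inhibitors against each other. Differences are log2 fold changes with SE, and levels are deposited FPKM as mean ± SD. Each edgeR SE was worked back from the log2 difference and the quasi-likelihood F statistic. The 95% intervals were built on it with a t distribution and are approximate.

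Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation and fry beside it, on 31 lists with enough tested genes (the T cell list had 2 and was not tested). Camera asks whether a list moves relative to the other genes. With an estimated correlation, the macrophage and neutrophil lists in BAPN vs. PBS were the 2 calls that held, and neither held without PBS replicate 3 (camera adjusted p = 0.0763 for both). Members were counted over all genes and adjusted over the list alone. Lists of kidney, liver and pluripotent cell genes were added after the data were seen, of which the kidney list had 15 of 20 genes tested and the last had too few to give a level.

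Named genes were chosen by rule: 15 target and disease genes, the 8 largest passing changes each way with groups that did not overlap and no predicted gene models, filled to 4 by smallest p where fewer passed, and up to 4 members by smallest p of each list reported. Umod, Slc12a1, Kap, H2-Ea, Alb, Acta1, Igkc, Hspa1b, Fgfbp3 and the levels of Gpx3, Klk10 or C1qb outside the comparisons that the rule names were chosen after their values were seen.

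Alternatives were another pseudocount, no or a stricter filter on FPKM, FPKM rescaled to a common total (TPM), quantile normalisation, fits with only the groups compared, a replicate block, robust fitting, array weights, sums of transcript FPKM and leaving out each library. Limma on log2(FPKM + 1), DESeq2 1.42.0, its size factors in edgeR, the settings that use the library sets, and list tests with each library left out were chosen after seeing the data. The sets came from a rule that parts libraries by genes with a gap of at least 1 log2 unit between them, also chosen after seeing the data. The pipeline was tested on simulated data with 200 changed genes among 13294: for BAPN vs. PBS it recovered 11.9% of genes changed 1.5-fold, 65.7% changed 2-fold and 81.8% changed 4-fold, with 5 false calls. Genes were drawn independently there and 111 passed, against 31 in the data, so these shares may be too high for the data.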

Results

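Transcript levels were measured by bulk RNA sequencing in the ascending aorta of C57BL/6 mice at 6 weeks of an aneurysm model. The model uses β-aminopropionitrile (BAPN), an inhibitor of the lysyl oxidases that cross-link collagen and elastin. There were 3 PBS libraries, 4 BAPN libraries, 3 libraries of BAPN with Cilengitide, a cyclic RGD pentapeptide that binds αV integrins, and 4 of BAPN with SB273005, which the labels also call an integrin αV inhibitor. The labels give no dose of either compound. Total counts ran from 49027885 to 72584877 per library. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples. The question put by the design is how BAPN changed the aorta and how each inhibitor changed the BAPN-fed aorta.

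Transcripts typical of other tissues parted the libraries into 2 sets, a grouping found in the data and not given by the labels. Umod, a kidney tubule gene, was at 7.73 to 11.6 FPKM in the 6 libraries of PBS and of SB273005 replicates 1 to 3, and at 19.8 to 25.8 FPKM in the other 8 libraries. H2-Ea, an MHC class II gene that C57BL/6 mice are known not to express, had 0 counts in each of the first 6 libraries and 83 to 130 in each of the other 8. It is one of the 30 genes by which the sets were chosen, so its parting is no test of them. PBS lies wholly in the first set, and BAPN and Cilengitide lie wholly in the second, so in BAPN vs. PBS and in Cilengitide vs. PBS the set and the group cannot be told apart. Within the first set, SB273005 replicates 1 to 3 could be compared with PBS, and those values stand beside the results. They use the same 3 PBS libraries as the other comparisons with PBS, so they are not independent of them.

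**Figure D1:**
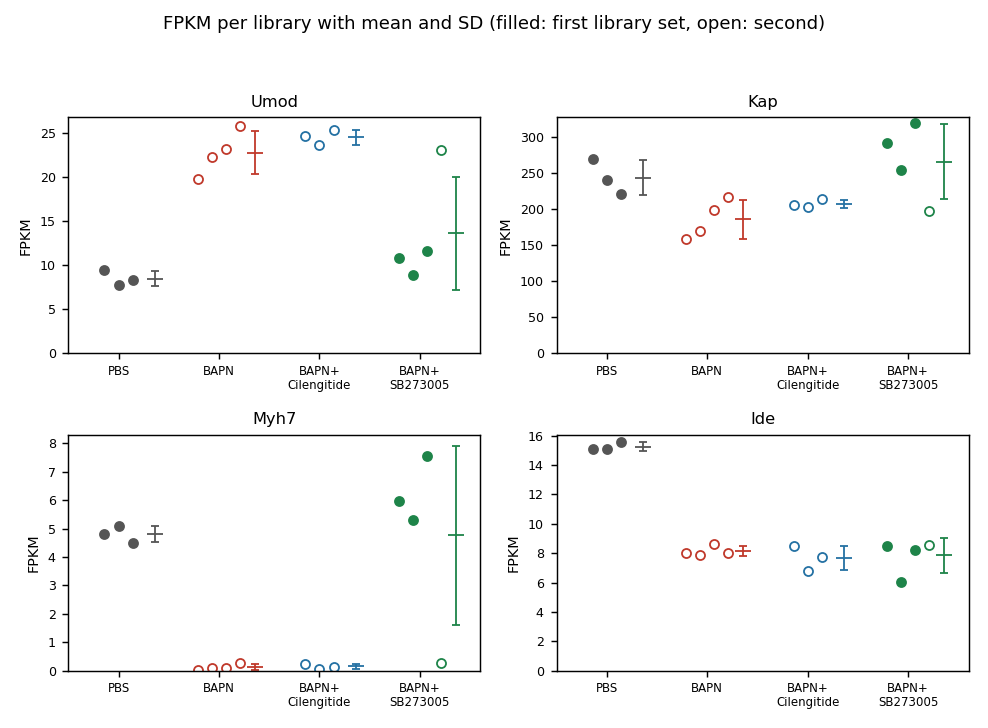
Expression (FPKM, linear axes from 0) of Umod, Kap, Myh7 and Ide in each of the 14 libraries by group, with the mean and SD of each group; filled points are the first library set and open points the second. Umod is higher in the second set, while Myh7 and Kap are higher in the first, Kap by a narrow gap (221 against 217 FPKM). SB273005 replicate 4 stands beside the BAPN libraries in each of them. Ide is at 6.07 to 8.64 FPKM in the 11 BAPN-fed libraries of both sets and at 15.1 to 15.6 in PBS.

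Macrophage and chemokine genes were higher in BAPN than in PBS aortas. Mrc1, the macrophage mannose receptor, was at 9.09 ± 1.79 FPKM (SD, n = 4) vs. 2.53 ± 0.32 (n = 3), a log2 difference of 1.84 ± 0.26 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0181). Fcgr3, an Fcγ receptor, rose from 4.77 ± 0.774 to 19.2 ± 7.21 FPKM, and C5ar1, the receptor of complement C5a, from 0.875 ± 0.176 to 4.09 ± 1.21 (edgeR adjusted p = 0.0461 and 0.0363). The chemokine genes Ccl9 and Ccl6 rose by 2.17 ± 0.33 and 1.97 ± 0.34 on the log2 scale (edgeR adjusted p = 0.0239 and 0.04). Ccl17, another chemokine gene, had 127 counts over the BAPN libraries and 0 over PBS, so it was at least 31.6-fold higher against a floor of 3 counts over the PBS group, a bound that covers counting error only (edgeR adjusted p = 0.0391). Ms4a4a, Ms4a6d, Ifi207 and Npl, the gene of a sialic acid catabolic enzyme, also rose, by 2.07 ± 0.22, 2.42 ± 0.38, 2.17 ± 0.29 and 2.30 ± 0.37 (edgeR adjusted p = 0.00542, 0.0348, 0.0152 and 0.0348). Ms4a4a, Ms4a6d, Ifi207, Ccl6 and Ccl9 belong to families of close paralogs, so their counts are uncertain where reads are shared.

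The 19 macrophage and monocyte genes measured were all above PBS, with a median log2 difference of 1.49. Of these, 1 passed over all genes and 18 passed adjusted over the list alone (camera adjusted p = 8.19e-29 for the list, adjusted p = 0.0203 with an estimated correlation). The neutrophil list had a median of 2.66 over 4 genes, with 0 passing over all genes and 3 passing adjusted over the list alone (camera adjusted p = 2.22e-09, adjusted p = 0.0203 with an estimated correlation); S100a8, a calprotectin subunit, was 3.83 ± 0.81 higher (edgeR adjusted p = 0.0537). With an estimated correlation both calls ended without PBS replicate 3 (camera adjusted p = 0.0763 for both). The erythroid list, made of red blood cell genes, had a median of 2.54 in the same comparison, or 1.60 without BAPN replicate 3, and its 5 genes passed adjusted over the list alone (camera adjusted p = 0.000691, adjusted p = 0.372 with an estimated correlation). Of 19 cytokine and chemokine genes, 2 rose over all genes tested and 10 adjusted over the list alone, where 1 fell (median 1.32, and 2.15 without PBS replicate 1; camera adjusted p = 7.53e-15, adjusted p = 0.0601 with an estimated correlation). Among 28 collagen and matricellular genes 27 were above PBS, with a median of 0.60 (0.30 without BAPN replicate 1), 0 past the edgeR threshold over all genes and 3 adjusted over the list alone (camera adjusted p = 2.11e-09, adjusted p = 0.311 with an estimated correlation). The fibroblast list had a median of 0.55, or 0.26 without PBS replicate 1 (camera adjusted p = 2.48e-05, adjusted p = 0.306 with an estimated correlation). Brown adipocyte genes were at 0.72 and cardiomyocyte genes at −0.48 (camera adjusted p = 0.00429 and 0.0158, adjusted p = 0.372 and 0.522 with an estimated correlation). The former call ended without PBS replicate 1 or 3 or BAPN replicate 4 (medians 0.51, 0.48 and 0.41, camera adjusted p = 0.0616, 0.0519 and 0.0599), the latter without PBS replicate 2 or BAPN replicate 1 (medians 0.12 and −0.37, camera adjusted p = 0.584 and 0.0768). The brown adipocyte median was 1.84 without PBS replicate 2, and the cardiomyocyte one −0.83 without PBS replicate 1 (camera adjusted p = 0.000265). Lox, the lysyl oxidase gene, was at 143 ± 77.6 FPKM vs. 52.6 ± 14.5 and did not pass (log2 1.44 ± 0.38, edgeR adjusted p = 0.115). Spp1, osteopontin, was at 60.1 ± 40.5 FPKM vs. 7.14 ± 1.40 and did not pass either (log2 3.08 ± 0.69, edgeR adjusted p = 0.0663).

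Ide, insulin-degrading enzyme (ENSMUSG00000056999, chromosome 19, 37268743 to 37330613, mm10), fell from 15.3 ± 0.294 FPKM in PBS to 8.14 ± 0.341 in BAPN (log2 −0.90 ± 0.11, edgeR adjusted p = 0.00659). Prdm6, a smooth muscle transcriptional repressor, fell from 23.7 ± 1.13 to 15.0 ± 1.28 FPKM and Tsc22d1 from 50.7 ± 5.34 to 29.5 ± 3.95 (edgeR adjusted p = 0.0352 for both). Abcb9, Arhgef3 and Foxp4 fell by 0.54, 0.49 and 0.45 on the log2 scale (edgeR adjusted p = 0.0492, 0.0461 and 0.0492). Myh7, a cardiac myosin heavy chain gene that parts the library sets, was 5.31 ± 0.91 log2 units lower in BAPN, and the kidney genes Umod and Slc12a1 were higher, at 22.7 vs. 8.49 and 1.82 vs. 0.906 FPKM. The 15 contractile smooth muscle genes had a median of −0.28 and 0 passed over all genes or adjusted over the list alone in edgeR (camera adjusted p = 0.0146, adjusted p = 0.657 with an estimated correlation), and this call ended without PBS replicate 3 or BAPN replicate 1 (medians −0.28 and −0.15, camera adjusted p = 0.0843 and 0.0768). Itgav, the gene of the inhibited subunit, was at 9.94 ± 0.558 FPKM vs. 8.76 ± 1.12 (log2 0.19 ± 0.14, edgeR adjusted p = 0.686). Over all 13294 genes tested, 31 passed, 24 higher and 7 lower, and 2010 genes (15.1%, 5.71% by chance) had groups that did not overlap. Limma on FPKM rescaled to a common total called 18 higher and 2 lower, and on quantile-normalised values 13 and 7. Within the first set the values of SB273005 vs. PBS were 1.66 for Mrc1, 2.78 for Fcgr3, 1.72 for Ccl9, −0.94 for Ide and −0.87 for Prdm6 (edgeR adjusted p = 0.0293, 0.017, 0.0421, 0.0293 and 0.0292), while Ccl6, Npl, Gpx3, Arhgef3 and Foxp4 were at 1.02, 1.61, 0.68, −0.37 and −0.28 and did not pass there (edgeR adjusted p = 0.133, 0.101, 0.113, 0.118 and 0.245). Myh7 and Umod were at 0.45 and 0.38 in that comparison (edgeR adjusted p = 0.149 and 0.145). It shares its PBS libraries with BAPN vs. PBS, from which the genes above were picked, so a repeat there is not independent support.

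The BAPN count of 31 depends on single libraries: leaving out 1 at a time gave 2 (without PBS replicate 2) to 186 genes (without SB273005 replicate 2, which enters the shared estimate of spread), and each omission except that of BAPN replicate 3 (27 genes) moved it by over 1.5 times. DESeq2 called 480 genes, 349 higher and 131 lower, and edgeR with the library set as a term, which rests on SB273005 replicate 4, called 3, of which 0 were among the 31.

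Among the genes that rose in BAPN with Cilengitide vs. PBS were matrix, cross-linking and macrophage genes. Lox was at 193 ± 11.2 FPKM (SD, n = 3) vs. 52.6 ± 14.5 (n = 3), and Loxl3, a lysyl oxidase paralog, at 40.9 ± 6.45 vs. 21.2 ± 0.661 (log2 1.92 ± 0.40 and 0.99 ± 0.16, edgeR adjusted p = 0.0185 and 0.00697). Fn1, fibronectin, rose from 123 ± 22.3 to 457 ± 222 FPKM, and Mmp2, a gelatinase, from 71.1 ± 13.9 to 249 ± 46.2 (edgeR adjusted p = 0.0232 and 0.0225). Spp1 rose to 172 ± 134 FPKM (log2 4.63 ± 0.76) and Comp, a cartilage matrix protein, from 10.8 ± 0.492 to 146 ± 100 (log2 3.79 ± 0.61; edgeR adjusted p = 0.00723 and 0.00685). Fmod, a collagen-binding proteoglycan, and Tnc, tenascin C, rose by 2.67 ± 0.40 and 2.06 ± 0.31, and Thbs1, thrombospondin 1, by 4.28 ± 0.84 (edgeR adjusted p = 0.00554, 0.00567 and 0.0143).

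Of the 28 collagen and matricellular genes 10 rose over all genes tested and 20 adjusted over the list alone in Cilengitide vs. PBS, with a median of 1.04 (camera adjusted p = 3.42e-14, adjusted p = 0.119 with an estimated correlation). The elastic fibre list had 9 of 19 genes higher and 11 adjusted over the list alone, with Ltbp2, a latent TGF-β binding protein gene, at 2.06 ± 0.37 (edgeR adjusted p = 0.0103; camera adjusted p = 1.63e-09 for the list, adjusted p = 0.13 with an estimated correlation). Among 26 matrix proteases and inhibitors 9 rose and 15 adjusted over the list alone, among them Timp1 (2.27 ± 0.42) and cathepsin K, Ctsk (1.90 ± 0.39; edgeR adjusted p = 0.0124 and 0.0175; camera adjusted p = 7.22e-11, adjusted p = 0.11 with an estimated correlation). Of the macrophage genes 13 of 19 rose and 15 adjusted over the list alone; C1qb, a complement C1q chain, was at 142 ± 47.0 FPKM vs. 28.3 ± 6.63, and Cd14, the lipopolysaccharide co-receptor, rose by 2.44 ± 0.32 (edgeR adjusted p = 0.00554 and 0.00394). For that list the median was 2.05 (camera adjusted p = 7.48e-26, adjusted p = 0.0603 with an estimated correlation). The 19 integrin genes had a median of −0.01 (camera adjusted p = 0.113), and 3 of them rose: Itgam, a leukocyte integrin chain, by 2.86 ± 0.48, Itga11, a collagen-binding one, by 3.10 ± 0.63 and Itga6, a laminin-binding one, by 2.17 ± 0.53, while Itgav stood at 0.04 ± 0.15 (edgeR adjusted p = 0.00747, 0.0164, 0.0338 and 0.922). Of other cell types, camera called fibroblast (median 0.32), adipocyte (0.79) and mesothelial (−1.29) lists here (camera adjusted p = 0.0106, 0.0376 and 0.0124, adjusted p = 0.546, 0.764 and 0.578 with an estimated correlation). These calls ended without PBS replicate 1 or Cilengitide replicate 3, without PBS replicate 3 or Cilengitide replicate 1, and without PBS replicate 2, in that order (medians 0.21, 0.36, 0.65, 0.43 and −0.72, camera adjusted p = 0.266, 0.066, 0.198, 0.355 and 0.09), and the fibroblast median was 0.50 without PBS replicate 3. The mitochondrially encoded list had a median of −0.75 (camera adjusted p = 0.000772, adjusted p = 0.622 with an estimated correlation). Clec4d, Gpr176, Pkp1, Cx3cr1 and S100a8 had the largest rises under the naming rule that were not named above, at 5.23, 4.84, 4.33, 4.33 and 4.30 (edgeR adjusted p = 0.0103, 0.00554, 0.0126, 0.0176 and 0.0137).

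Among the largest falls under the naming rule from PBS to Cilengitide were an immunoglobulin gene and genes typical of the liver. Igkv3-2, an immunoglobulin segment, had 903 FPKM in PBS replicate 1 and 2.97 and 3.03 in the other PBS libraries, and 7 counts over the Cilengitide group (edgeR adjusted p = 0.0476). The liver genes Mup20 and Hpx, haemopexin, were at −5.47 ± 1.33 and −4.99 ± 1.18 (edgeR adjusted p = 0.0329 and 0.0295), with 97.2, 39.2 and 3.70 FPKM of Mup20 in PBS replicates 1 to 3. Mup20 has near-identical paralogs. Egln3, an oxygen-sensing prolyl hydroxylase, fell by 1.18 ± 0.24 (edgeR adjusted p = 0.0176). In total 742 genes passed, 529 higher and 213 lower, and 4322 (32.5%, 10% by chance) had groups that did not overlap; limma on rescaled FPKM called 485 higher and 64 lower and on quantile-normalised values 359 and 245. The count fell to 435, 109 and 379 without PBS replicate 1, 2 or 3 and to 194 and 211 without Cilengitide replicate 1 or 2, rose to 1249 without SB273005 replicate 2, was 1465 with DESeq2 and 5 with the library set as a term (2 of them among the 742).

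In BAPN with SB273005 vs. PBS, matrix and macrophage genes were among those that rose, and contractile genes among those that fell. Lox was at 195 ± 68.7 FPKM (SD, n = 4) vs. 52.6 ± 14.5 (n = 3), Mmp2 at 255 ± 98.3 vs. 71.1 ± 13.9 and Eln, elastin, at 2840 ± 986 vs. 1100 ± 70.2 (edgeR adjusted p = 0.00857, 0.00957 and 0.0313). Spp1, Comp and Fmod rose by 4.01 ± 0.72, 3.42 ± 0.59 and 2.54 ± 0.39 (edgeR adjusted p = 0.0058, 0.00475 and 0.00327). Lmod1, which nucleates smooth muscle actin filaments, fell from 188 ± 10.1 to 73 ± 30.8 FPKM, and Myh11, the smooth muscle myosin heavy chain, from 753 ± 54.2 to 286 ± 160 (edgeR adjusted p = 0.0136 and 0.0494). Itgb3, the β3 integrin chain that pairs with αV, fell from 20.3 ± 2.60 to 9.63 ± 3.25 FPKM (log2 −1.03 ± 0.21, edgeR adjusted p = 0.00867), while Itgav stood at 8.54 ± 1.75 vs. 8.76 ± 1.12 (edgeR adjusted p = 0.943). Of the 19 integrin genes 3 rose and 2 fell, with a median of −0.06 (camera adjusted p = 0.905).

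Of 15 contractile genes 7 fell and 11 adjusted over the list alone in SB273005 vs. PBS, with a median of −1.12 (camera adjusted p = 2.18e-07, adjusted p = 0.43 with an estimated correlation). Synpo2 fell by 1.47 ± 0.37 and Smtn, smoothelin, by 0.85 ± 0.23, while Acta2, smooth muscle actin, at 2590 ± 1460 vs. 5340 ± 698 FPKM, did not pass (edgeR adjusted p = 0.0241, 0.0293 and 0.162). SB273005 replicate 2 had 548 FPKM of Acta2, against 2720 to 3990 in the others of its group, and the highest level of mitochondrially encoded genes of all 14 libraries (1.56 log2 units), and without it the contractile median was −0.84 (camera adjusted p = 3.57e-08, adjusted p = 0.227 with an estimated correlation). Markers of other cell types were also called in this comparison: endothelial genes had a median of 0.73, with 3 of 13 higher, and adipocyte genes one of 1.00, with 1 of 14 higher (camera adjusted p = 0.0227 and 0.0237, adjusted p = 0.73 and 0.782 with an estimated correlation). The former call ended without PBS replicate 1 or SB273005 replicate 2 (medians 0.58 and 0.45, camera adjusted p = 0.16 and 0.0891), the latter without PBS replicate 3 or SB273005 replicate 1 or 3 (medians 0.89, 0.68 and 0.81, camera adjusted p = 0.123, 0.193 and 0.164). Of the 28 collagen and matricellular genes 17 rose and 18 adjusted over the list alone, led by Cthrc1 (5.05 ± 1.25) and the collagen genes Col11a1 (4.64 ± 1.30) and Col8a1 (3.71 ± 0.81; edgeR adjusted p = 0.0219, 0.035 and 0.0131). That list's median was 1.10 (camera adjusted p = 8.13e-08, adjusted p = 0.43 with an estimated correlation). The macrophage list had 15 of 19 genes higher, 16 adjusted over the list alone, and a median of 2.03 (camera adjusted p = 2.77e-19, adjusted p = 0.073 with an estimated correlation).

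Interferon response genes had a median of 1.09 in SB273005 vs. PBS, with 6 of 13 higher and 9 adjusted over the list alone (camera adjusted p = 0.000188, adjusted p = 0.542 with an estimated correlation), and a median of 0.70 without SB273005 replicate 1. Irf7, an interferon regulatory factor, rose by 1.88 ± 0.42 and Bst2, tetherin, by 0.92 ± 0.21 (edgeR adjusted p = 0.014 and 0.0165). The unfolded protein response list had 3 of 16 genes higher, 3 also adjusted over the list alone, with Trib3 at 1.29 ± 0.23 (edgeR adjusted p = 0.00585) and a median of 0.70, or 0.42 without SB273005 replicate 4 (camera adjusted p = 0.000407, adjusted p = 0.542 with an estimated correlation). Other large falls were of Klk10, a kallikrein-related peptidase (−2.97 ± 0.43), Rab17 (−2.93 ± 0.42), the α1D adrenergic receptor Adra1d (−2.10 ± 0.33) and Smim5 (−2.10 ± 0.23; edgeR adjusted p = 0.00243, 0.00229, 0.00376 and 0.000602). Atcayos, named as an antisense transcript, was at −2.96 ± 0.37, and without a stated strand setting its reads cannot be told from those of an overlapping gene (edgeR adjusted p = 0.00166).

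Over all genes 1754 passed in SB273005 vs. PBS, 1039 higher and 715 lower, and 3067 (23.1%, 5.71% by chance) had groups that did not overlap; with quantile-normalised values in limma the split was 760 higher and 858 lower, and on rescaled FPKM 409 and 320. In the first set alone, 3 against 3 libraries, edgeR called 532 genes, 512 of them among the 1754, with medians of 2.16 for the macrophage list, 1.15 for collagens and −1.31 for contractile genes (camera adjusted p = 7.41e-26, 1.97e-09 and 3.84e-08, and adjusted p = 0.263, 0.491 and 0.55 with an estimated correlation). There Spp1, Fmod and Mmp2 passed at 4.17, 2.69 and 2.00 (edgeR adjusted p = 0.0292, 0.0207 and 0.0448), while Lox, Eln, Itgb3, Lmod1 and Myh11 were at 1.93, 1.42, −1.08, −1.50 and −1.59 and did not (edgeR adjusted p = 0.0503, 0.163, 0.099, 0.0831 and 0.172). Without SB273005 replicate 2 the first set gave 423, and over all libraries the count was 1107, 498 and 932 without PBS replicate 1, 2 or 3.

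**Figure D2:**
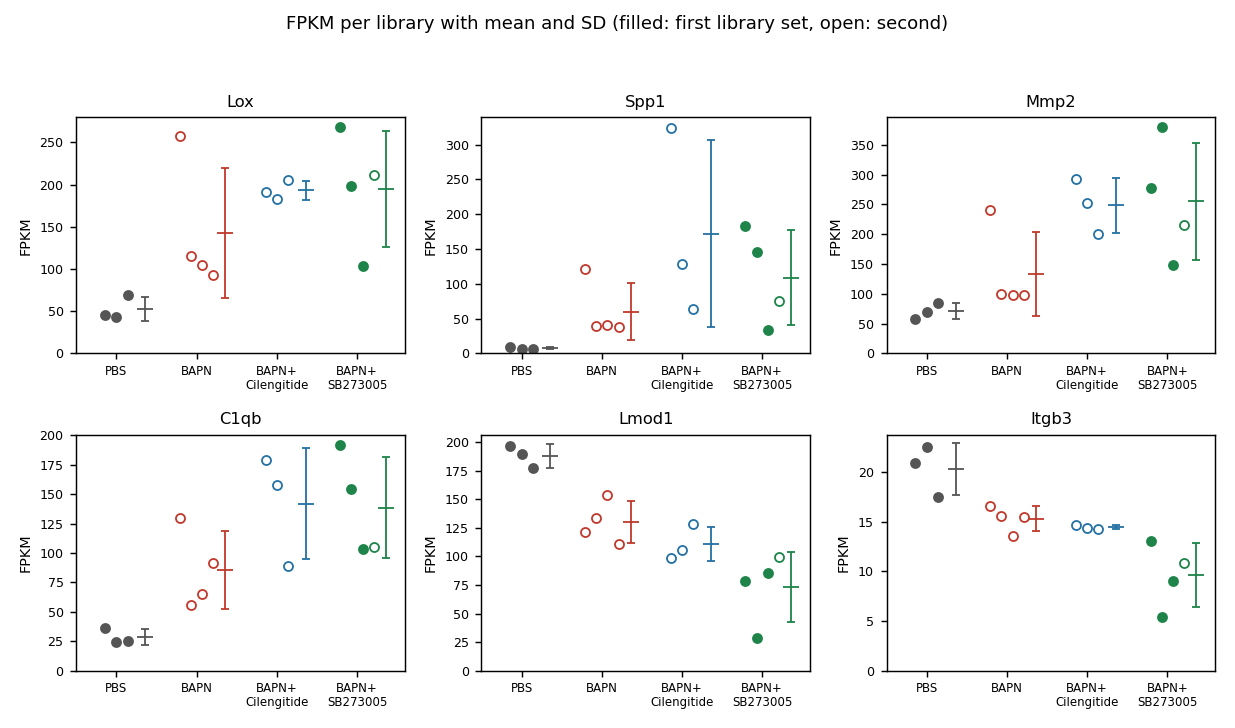
FPKM (linear axes from 0) of Lox, Spp1, Mmp2, C1qb, Lmod1 and Itgb3 in each of the 14 libraries by group, with the mean and SD of each group; filled points are the first library set and open points the second. Mean Lox is 52.6 in PBS, 143 in BAPN, 193 with Cilengitide and 195 with SB273005, and BAPN replicate 1 stands at 258 in its group.

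Between BAPN with Cilengitide and BAPN alone, no single gene passed the test. The genes with the smallest p were Daam2, a formin-family gene of Wnt signalling, at 2.00 ± 0.456 FPKM (SD, n = 3) vs. 1.08 ± 0.209 (n = 4), Cst3, cystatin C, at 1400 ± 165 vs. 818 ± 106, Cilp2 at 3.59 ± 1.38 vs. 1.66 ± 0.246 and Stk32b at 6.96 ± 0.702 vs. 4.09 ± 0.508. On the other side were Bmx, a tyrosine kinase gene, at 1.28 ± 0.345 vs. 3.11 ± 0.586 FPKM, Adh7 at 0.366 ± 0.0282 vs. 1.10 ± 0.421, Gkn3 at 1.15 ± 0.445 vs. 3.16 ± 1.02 and B3gnt5 at 0.679 ± 0.0739 vs. 1.33 ± 0.388. All 8 had an edgeR adjusted p of 0.795. Spp1 was 1.56 higher (95% interval 0.24 to 2.87), Fn1 0.95 (0.11 to 1.78), Mmp2 0.94 (0.15 to 1.72) and Itgav −0.15 (−0.45 to 0.15), and none of these passed (edgeR adjusted p = 0.795, 0.795, 0.795 and 0.866).

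Camera with a preset correlation called matrix and cartilage lists in Cilengitide vs. BAPN, and none of these calls held with an estimated correlation. The collagen list had 23 of 28 genes above BAPN and a median of 0.41, and the elastic fibre list 17 of 19 and 0.26 (camera adjusted p = 5.69e-08 and 3.93e-06, adjusted p = 0.301 for both with an estimated correlation), and without BAPN replicate 1 these medians were 0.69 and 0.43. For the 11 chondrogenic and osteogenic genes the median was 1.22 (0.75 without Cilengitide replicate 1), with 0 past the edgeR threshold over all genes and 6 adjusted over the list alone (camera adjusted p = 3.93e-06, adjusted p = 0.301 with an estimated correlation). Comp was 2.17 ± 0.52 and the osteoblast factor Runx2 1.22 ± 0.41 higher, both short of the threshold (edgeR adjusted p = 0.795), and Col2a1, the cartilage collagen, was at 47.2 FPKM in Cilengitide replicate 1 and at 2.35 and 1.57 in the other Cilengitide libraries. The macrophage list had a median of 0.58 (camera adjusted p = 1.01e-05, adjusted p = 0.301 with an estimated correlation), and the erythroid list one of −2.46 (camera adjusted p = 1.33e-05, adjusted p = 0.301 with an estimated correlation), with Hbb-bs, β-globin, at 1870 FPKM in BAPN replicate 3 against 159 to 521 in the other BAPN libraries and a median of −1.53 without it. Cardiomyocyte genes had a median of 1.16 between these groups, which share a library set, or 0.32 without Cilengitide replicate 1, and mesothelial genes one of −0.87 (camera adjusted p = 5.82e-05 and 0.014, adjusted p = 0.301 and 0.643 with an estimated correlation). The mesothelial call ended without BAPN replicate 1 or 2 or Cilengitide replicate 1 or 3 (medians −0.86, −0.35, −0.70 and −0.93, camera adjusted p = 0.0765, 0.285, 0.126 and 0.0512). The mitochondrially encoded list had a median of −0.48 (camera adjusted p = 0.00052, adjusted p = 0.677 with an estimated correlation). EdgeR called 0 genes at an adjusted p of 0.05, with 807 at an unadjusted p under 0.05, limma 0 and DESeq2 21 (8 higher, 13 lower), and without Cilengitide replicate 2 edgeR called 1. Both groups lie in the second library set, and 1312 genes (9.87%, 5.71% by chance) had groups that did not overlap.

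Between BAPN with SB273005 and BAPN alone 4 genes differed; SB273005 replicates 1 to 3 lie in the first library set and BAPN in the second. Slc5a3, the sodium/myo-inositol cotransporter, rose from 1.99 ± 0.315 (SD, n = 4) to 3.86 ± 0.884 FPKM (n = 4), a log2 difference of 1.01 (95% interval 0.69 to 1.33; edgeR adjusted p = 0.0468). Inka2 fell from 6.94 ± 1.12 to 2.72 ± 0.492 FPKM, Igsf9 from 5.36 ± 0.495 to 2.60 ± 0.501 and Kcnh2, the hERG-type potassium channel gene, from 19.8 ± 1.68 to 11.3 ± 1.98 (log2 −1.30, −0.99 and −0.77, edgeR adjusted p = 0.0243, 0.0468 and 0.0468). With the library set as a term, which rests on SB273005 replicate 4, Slc5a3 was at 1.40 and passed, and Inka2, Igsf9 and Kcnh2 were at −1.04, −1.24 and −0.76 and did not (edgeR adjusted p = 0.00793, 0.393, 0.129 and 0.503). Short of the threshold were Stk32b at 1.00 ± 0.16, Hhipl1 at 0.66 ± 0.11 and Bdkrb2, the bradykinin B2 receptor, at −1.46 ± 0.23 (edgeR adjusted p = 0.0514 for each), and Myh7, which parts the library sets, at 5.35 ± 0.90 (edgeR adjusted p = 0.0516). Mmp2 was 1.00 higher (95% interval 0.26 to 1.74) and Itgb3 −0.62 (−1.04 to −0.21), and neither passed (edgeR adjusted p = 0.215 and 0.197).

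Contractile genes had a median of −0.80 in SB273005 vs. BAPN, with 0 of 15 past the edgeR threshold and 1 lower adjusted over the list alone (camera adjusted p = 3.85e-07, adjusted p = 0.633 with an estimated correlation). Without SB273005 replicate 2 that median was −0.54, and with the library set as a term −0.26 (camera adjusted p = 2.03e-06 and 0.205). Interferon response genes were at 0.79 and endothelial genes at 0.59 (camera adjusted p = 8.29e-05 and 0.00402, adjusted p = 0.633 for both with an estimated correlation), and at −0.09 and −0.02 with the set as a term (camera adjusted p = 0.893 for both). Without SB273005 replicate 1 the interferon median was 0.31, and without replicate 2 the endothelial one was 0.23. The collagen list was at 0.40 and at 0.41 with that term (camera adjusted p = 0.0102 and 0.000459, adjusted p = 0.633 and 0.869 with an estimated correlation; the former call ended without BAPN replicate 2 or 4 or SB273005 replicate 1 or 4, at camera adjusted p = 0.0567, 0.0594, 0.149 and 0.11, and the median was 0.66 without BAPN replicate 1), and the macrophage list at 0.69 and 0.19 (camera adjusted p = 0.00271 and 0.183, adjusted p = 0.633 for the former with an estimated correlation). Cardiomyocyte genes, some of which part the sets, were at 1.41 (camera adjusted p = 0.000408, adjusted p = 0.633 with an estimated correlation). Skeletal muscle, erythroid and brown adipocyte genes were at −1.58, −1.47 and −0.82 (camera adjusted p = 0.0119, 0.0122 and 0.00774, adjusted p = 0.633 for each with an estimated correlation). The first 2 calls ended without BAPN replicate 3 (medians −0.45 and −0.50) and the last without BAPN replicate 4 (−0.24; camera adjusted p = 0.206, 0.126 and 0.114). Leaving out SB273005 replicate 1 or 3 also ended the first call, replicate 2 or 3 the second and replicate 2 the last (medians −1.28, −1.29, −1.18, −1.12 and −0.56, camera adjusted p = 0.107, 0.0835, 0.0515, 0.12 and 0.0687), and without replicate 4 the erythroid median was −2.25. The mitochondrially encoded list was at 0.67 (camera adjusted p = 0.00266, adjusted p = 0.633 with an estimated correlation), and its call ended without BAPN replicate 1 or SB273005 replicate 2 (medians 0.49 and 0.13, camera adjusted p = 0.0663 and 0.356). DESeq2 called 395 genes, limma 15 and limma on quantile-normalised values 1, which was lower; the set as a term gave 12 in edgeR, 1 of them among the 4. Leaving out 1 library gave 0 to 79 genes, the highest without SB273005 replicate 4 and 0 without PBS replicate 2, BAPN replicate 2 or 3, Cilengitide replicate 2 or SB273005 replicate 1, and only the omission of SB273005 replicate 3 (3 genes) stayed within 1.5 times of 4.

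The inhibitors were also set directly against each other, SB273005 vs. Cilengitide in BAPN-fed mice, with doses that the labels do not state. Of the 15 disease and target genes fixed beforehand, 14 had a 95% interval of the difference that included 0, and 9 had one that lay within 1 log2 unit of 0. Itgav differed by −0.02 (−0.32 to 0.28), Lox by 0.03 (−0.75 to 0.82), Mmp2 by 0.07 (−0.73 to 0.86), Spp1 by −0.62 (−1.93 to 0.68) and Acta2 by −0.70 (−1.69 to 0.28). The exception was Itgb3, at 9.63 ± 3.25 FPKM (SD, n = 4) with SB273005 and 14.5 ± 0.213 (n = 3) with Cilengitide (log2 −0.58, interval −1.02 to −0.14), which did not pass over all genes (edgeR adjusted p = 0.5). Herc6, an interferon-induced gene, had the smallest p, at 1.13 ± 0.104 vs. 0.501 ± 0.0269 FPKM (log2 1.19, interval 0.78 to 1.60; edgeR adjusted p = 0.37), followed on that side by Prmt2 at 0.77 ± 0.15, Myh7, which parts the library sets, at 5.02 ± 1.00 and Zfp236 at 0.42 ± 0.09 and on the other by Fbxo32, a muscle ubiquitin ligase gene, at −1.08 ± 0.21 and Eef2k at −0.67 ± 0.15 (edgeR adjusted p = 0.5 for each).

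Among gene groups, the median of interferon response genes was 1.00 and that of endothelial genes 0.63 in SB273005 vs. Cilengitide, and that of contractile genes −0.53 (camera adjusted p = 3.77e-06, 4.48e-06 and 4.26e-06, adjusted p = 0.61, 0.61 and 0.685 with an estimated correlation). Isg15 and Ifit1, both interferon-induced, were at 1.47 ± 0.52 and 1.56 ± 0.54, and 4 of the 13 interferon genes passed adjusted over the list alone, with 0 over all genes tested in edgeR. SB273005 replicate 2 had the lowest contractile level, −1.97, where the others of its group were at −0.528, 0.039 and 0.07, and without it the contractile median was −0.25 and the endothelial one 0.40 (camera adjusted p = 0.00332 and 0.00017). Without SB273005 replicate 1 the interferon median was 0.49, and without Cilengitide replicate 2 the endothelial one was 0.37 (camera adjusted p = 0.0116 and 0.00144). With the library set as a term the medians of the interferon, endothelial and contractile lists were −0.04, 0.10 and 0.02 (camera adjusted p = 0.855, 0.654 and 0.926). Macrophage genes differed by a median of 0.02 and collagens by −0.11 (camera adjusted p = 0.725 and 0.07). EdgeR called 0 genes, with 1224 at an unadjusted p under 0.05, limma 0 and DESeq2 39 (28 higher, 11 lower); edgeR called 15 without SB273005 replicate 4, 1 without Cilengitide replicate 2, and 12 with the set as a term. In this comparison 840 genes (6.32%, 5.71% by chance) had groups that did not overlap.

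**Figure D3:**
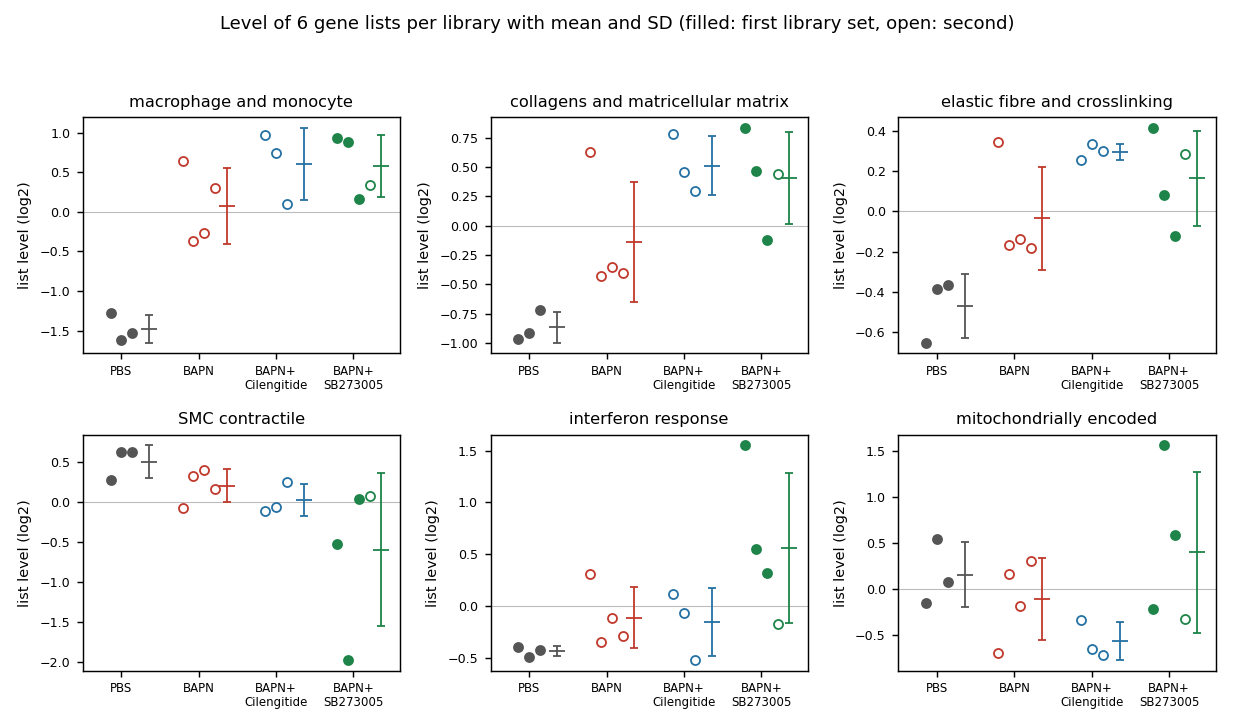
Level of 6 gene lists (log2, mean over the genes of a list, relative to its mean over all 14 libraries) in each library by group, with the mean and SD of each group; filled points are the first library set and open points the second. The macrophage level is −1.48 on average in PBS and 0.0748 in BAPN, 0.605 with Cilengitide and 0.577 with SB273005, and SB273005 replicate 2 lies apart at −1.97 in the contractile list.

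Whether the inhibitors moved genes back toward PBS was tested by correlating log2 differences across the 13294 genes, which are not independent replicates, with the 4 BAPN libraries split so that the differences shared none. A negative correlation would mean that genes moved back. Between BAPN vs. PBS and Cilengitide vs. BAPN the mean over 6 splits was 0.322 (0.164 to 0.479 over splits, Spearman 0.267, and below that range but positive with no filter on low FPKM), and with SB273005 it was 0.116 (−0.0708 to 0.304, Spearman 0.231). PBS and SB273005 replicates 1 to 3 share a library set and BAPN lies in the other, so the set enters the latter: it was 0.177 without the 30 genes that part the sets, and 0.0528 to 0.207 with 1 library left out. Unsplit, the values were 0.207 and −0.0136, where 50 simulations of unchanged groups gave −0.431 and −0.462 on average. The simulations drew each gene independently, while many genes vary together between these libraries. They show the effect of shared libraries, and do not measure how far chance can move such values. The unsplit covariances were 0.0356 and −0.0028 against simulated −0.0496 and −0.0492, differences of 0.0852 and 0.0464. Between the changes by the inhibitors themselves the split correlation was 0.263 (0.228 to 0.367, Spearman 0.271) and the unsplit one 0.548 against 0.462 simulated, with covariances of 0.0855 and 0.0489 and a difference of 0.0366. With 1 library left out that split correlation ran from 0.129 to 0.353, and with no filter on low FPKM it was lower still. Among genes chosen after their values were seen, Lox, Spp1, Mmp2, Fn1 and C1qb had mean FPKM farther from PBS with either inhibitor than with BAPN alone: Mmp2 was at 71.1, 134, 249 and 255 in PBS, BAPN, Cilengitide and SB273005, and C1qb at 28.3, 85.5, 142 and 139, and neither differed from BAPN past the threshold with either inhibitor. Mrc1 was at 9.09 FPKM in BAPN, 8.20 with Cilengitide and 7.43 with SB273005, which did not pass either (edgeR adjusted p = 0.948 and 0.613).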

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

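All tests of explanations here were chosen after the result they bear on was seen, as were the settings that use the library sets and the list tests with a library left out.

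Single libraries lay far from the others of their group in 11 of 92 tests, each of 1 list or gene within BAPN or SB273005. PBS and Cilengitide, with 3 libraries each, were not tested. Chance flags about 1 in 20 tests, or 4.6 here, but the lists and genes overlap and move together, so the 11 are not independent. BAPN replicate 1 was the highest of its group in 8: Itgav at 10.8 FPKM, Lox at 258, Eln at 3040, Spp1 at 121, Col3a1 at 978 and Mmp2 at 240, the collagen list at 0.625 and the elastic fibre list at 0.344 log2 units. SB273005 replicate 2 stood apart in 3 lists, focal adhesion at −0.808, neural and Schwann at 0.737 and glycolysis and hypoxia at −0.503.

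The inhibitors differed in 12 of 31 lists by camera on SB273005 vs. Cilengitide. Higher with SB273005 were the mitochondrially encoded list (median 1.14, camera adjusted p = 1.28e-11), mesothelial genes (1.31, 2.35e-05), interferon response (1.00, 3.77e-06), endothelial genes (0.63, 4.48e-06), immediate early and heat shock genes (0.36, 0.0116) and the unfolded protein response (0.33, 0.0281). Lower were contractile genes (−0.53, 4.26e-06), oxidative phosphorylation (−0.14, 0.01), focal adhesion (−0.23, 0.0101), oxidative stress (−0.14, 0.0108), glycolysis and hypoxia (−0.21, 0.0114) and integrins (−0.13, 0.0412). With an estimated correlation none held (edgeR called 0 genes here, with 1224 at an unadjusted p under 0.05 and 39 by DESeq2), the lowest adjusted p being 0.61. SB273005 replicate 2 stood apart in several: at 1.56 log2 units in the mitochondrially encoded list (−0.208, 0.585 and −0.325 in the others of its group), −1.97 in the contractile list and −0.543 in oxidative phosphorylation. Without it the calls of integrins (−0.04), focal adhesion (−0.05), oxidative phosphorylation (−0.04), glycolysis and hypoxia (−0.09) and oxidative stress (−0.09) ended (camera adjusted p = 0.132, 0.363, 0.607, 0.241 and 0.0502). The mitochondrially encoded list was then at 0.62, contractile genes at −0.25, endothelial genes at 0.40 and the unfolded protein response at 0.53 (camera adjusted p = 2.64e-09, 0.00332, 0.00017 and 2.38e-10). The unfolded protein response and the immediate early and heat shock list were highest of all libraries in SB273005 replicate 4 (0.852 and 0.889), and their calls ended without it (0.06 and 0.22, camera adjusted p = 0.65 and 0.294). Other single omissions also ended calls: the unfolded protein response without Cilengitide replicate 2 or 3 or SB273005 replicate 1, the immediate early and heat shock list, oxidative phosphorylation, and glycolysis and hypoxia without Cilengitide replicate 1, and integrins without Cilengitide replicate 1 or SB273005 replicate 3 or 4 (camera adjusted p = 0.101, 0.198, 0.172, 0.148, 0.0527, 0.128, 0.253, 0.0648 and 0.0616). Contractile, interferon, endothelial, mesothelial and mitochondrially encoded lists were called in each of the 7 omissions of a library of these groups, interferon at 0.49 without SB273005 replicate 1 and endothelial genes at 0.37 without Cilengitide replicate 2. With the library set as a term, where the SB273005 side rests on replicate 4, these 5 lists were not called (camera adjusted p = 0.926, 0.855, 0.654, 0.257 and 0.263), and the unfolded protein response and the immediate early and heat shock list, in which that library is the highest, were at 0.84 and 0.60 (camera adjusted p = 2.52e-16 and 9.67e-15, adjusted p = 0.153 and 0.0701 with an estimated correlation).

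Transcripts typical of other tissues parted PBS replicates 1 to 3 and SB273005 replicates 1 to 3 from the other 8 libraries: Kap was at 221 to 319 vs. 159 to 217 FPKM (higher in the first set, unlike Umod and the kidney mean) and Myh7 at 4.51 to 7.54 vs. 0.0329 to 0.261. The rule for this went through 3 forms, all set after seeing the data: the kidney mean (at most 1.37 vs. at least 1.57 log2 FPKM), genes with a gap of 0.5 (60, against 54 for the next split, PBS 1 to 3 with BAPN 2 to 4) and genes with a gap of 1 (30, against 21 for the next split, which adds BAPN replicate 3 to the first set). Transcripts carried over from other libraries of a batch are a candidate explanation: within PBS, BAPN and Cilengitide 18 kidney genes outside the defining ones varied by a median SD of 0.16, against 2.29 for skeletal muscle and 1.67 for liver genes, a ratio of 0.0717 to muscle where 0.5 was the bound, though low expression in the aorta itself would vary as little. An earlier form within the sets was dropped, since the sets partly fix it. Each of these groups also lies wholly in a single set, so that limit remains. For treatment as the cause, tests over 18 kidney genes decided nothing: SB273005 replicate 4 lay a median of 0.23 above replicates 1 to 3 and above all of them in 7, and was nearer to the BAPN and Cilengitide libraries in 14, where 13.5 plus a binomial SD of 1.84 were needed (a margin set after the value). In a last test, chosen after these, it was nearer to those libraries than to the first set in 30 of 31 genes, where 28.1 were needed. These genes were picked with replicate 4 left out, but the sets themselves had been formed with it. Leaving it out cannot close the gap of the 30 defining genes, so this value was nearly fixed beforehand and decides nothing. The criterion also asked every other library to lie with its own set, and BAPN replicate 3 did so in 27 of 49. Treatment therefore cannot be told apart from a batch by this criterion, which rests on the place of 1 library.

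Ide was lower in all 11 BAPN-fed libraries (6.07 to 8.64 FPKM) than in PBS (15.1 to 15.6). For SB273005, the library set as the cause is argued against by the fall of Ide within the first set (log2 −0.94 ± 0.15, edgeR adjusted p = 0.0293). That comparison uses the same PBS libraries as the one by which Ide was picked. A copy number difference of a segment holding Ide and Fgfbp3 between mouse colonies is a candidate explanation: Fgfbp3, its neighbour on chromosome 19, was at −0.80 ± 0.21 in BAPN vs. PBS (edgeR adjusted p = 0.113), while Btaf1, Cpeb3, Marchf5 and Exoc6 had a median of −0.01 (−0.16 to 0.23). BAPN feeding predicts the same 11 of 11 and stays open, since no library with another source of mice and the same feeding was analysed here. No genotype was analysed here. If the PBS mice came from another colony than the BAPN-fed mice, every comparison with PBS, also that within the first set, would be confounded with colony.

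The macrophage list was above PBS in each BAPN-fed group, in comparisons that share the same PBS libraries. With an estimated correlation it was called only in BAPN vs. PBS, and not there without PBS replicate 3. Of 28 collagen genes 10 and 17 passed over all genes with Cilengitide and SB273005, and in BAPN alone 3 passed adjusted over the list alone, with a median of 0.60, or 0.30 without BAPN replicate 1 (camera adjusted p = 2.11e-09, adjusted p = 0.311 with an estimated correlation). For SB273005, the library set as the whole cause is argued against by the macrophage list within the first set, with a median of 2.16. Its lower quartile was 1.83, and 18 of 19 genes were above PBS. These genes are not independent replicates, and the list was not called there with an estimated correlation. For BAPN and Cilengitide the set and the group cannot be told apart. A lower share of smooth muscle cells, which would raise endothelial genes alike, is also argued against as the whole cause: the macrophage minus the endothelial level was 1.60 (SD 0.46) above PBS over the BAPN-fed libraries, and 11 of 11 lay above the highest PBS library. As a part of the cause it is not excluded. With SB273005 the mean contractile level was −0.597 vs. 0.502 in PBS, and the endothelial level 0.408 vs. −0.215. The endothelial level was −0.104 in BAPN and −0.191 with Cilengitide. More adventitial tissue in the samples stays open, by a criterion set after the values were seen: the macrophage minus the fibroblast level was 1.44 (SD 0.57) above PBS, with 10 of 11 above the highest PBS library at 0.68 and BAPN replicate 2 below it at 0.58. For matrix genes these explanations were not tested apart from macrophage genes, and more macrophages in the wall may account for the macrophage part, as a hypothesis.

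Other splits of the same libraries were used to ask whether chance could give the counts. In BAPN vs. PBS 1 of 35 splits, the real one, gave as many as 31 genes (the highest other gave 21), and in SB273005 vs. PBS 1 of 35 gave 1754 (441, for PBS 1 to 3 with SB273005 replicate 4). This is the smallest share that 35 splits can give. It argues against chance in both without excluding it, since the criterion was set after the data and several comparisons were made without correction. Nor does it part BAPN from the library set in the former. Chance is less argued against for SB273005 vs. BAPN, where 3 of 35 splits gave as many as 4 genes and {BAPN 1, SB273005 1, 2 and 4} gave 48, which points to a structure of the samples. For the other contrasts between fed groups edgeR called 0 genes (807 and 1224 at an unadjusted p under 0.05, DESeq2 21 and 39), a count that all 35 of 35 splits must reach, so the splits say nothing of chance there. The highest other for Cilengitide vs. BAPN was 5, and for SB273005 vs. Cilengitide the split along the library sets, Cilengitide with SB273005 replicate 4, gave 35, which points to a structure of the samples, and the second set alone gave 34 with SB273005 replicate 4 as its group's only library. Cilengitide vs. PBS has 10 splits, too few for a share under 0.05, with 742 genes and 0 in the highest other. For lists, as many as the real count came from 11 of 35 splits in BAPN vs. PBS (18 lists, highest other 22), 24 of 35 in Cilengitide vs. BAPN (12, 18), 5 of 35 in SB273005 vs. BAPN (17, 20), 23 of 35 in SB273005 vs. Cilengitide (12, 19) and 9 of 35 in SB273005 vs. PBS (17, 22), so chance is not excluded for a count of lists. In Cilengitide vs. PBS 5 of 10 did (17, 22), again too few splits.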

How the results depend on the processing

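Limma on log2(FPKM + 1), DESeq2 and its size factors, all settings with library sets, and list tests with each library left out were chosen after seeing the data. For each value that moved, the cause was not tested unless stated. Counts are of genes called, for BAPN vs. PBS (31), SB273005 vs. BAPN (4), Cilengitide vs. PBS (742) and SB273005 vs. PBS (1754) unless another is named. With limma and a pseudocount of 0.1 the first was 72 and the second 14. With no filter, which tests more genes, they were 3, 0 (edgeR), 421 and 1006, the Cilengitide reversal correlation was 0.149 and that between the inhibitors 0.112. With a mean FPKM of 5 or more, which tests fewer genes, the last 3 counts were 1, 419 and 1148 and the correlation between inhibitors 0.347. Rescaled FPKM (TPM) gave 20 for BAPN vs. PBS and 729 for SB273005 vs. PBS, and moved the median of all genes by −0.165 in SB273005 vs. BAPN, −0.246 in SB273005 vs. Cilengitide, 0.148 in Cilengitide vs. PBS and −0.102 in SB273005 vs. PBS. Quantile normalisation gave 20 and 1 for the first 2 and 0.352 between inhibitors. Fits with only the groups compared, with fewer samples, gave 105, 0 (edgeR) and, for SB273005 vs. PBS, 534. Array weights gave 173, 14 and 1488. Sums of transcript FPKM gave 17 and 2 and a correlation of 0.335, and limma on log2(FPKM + 1) 15 and 15 and 0.338. DESeq2 gave 480, 395 and 1465, with 21 for Cilengitide vs. BAPN and 39 for SB273005 vs. Cilengitide. With the library set as a term the counts were 3 (0 shared with the 31), 12 (1 shared) and 5 (2 shared), and 12 for SB273005 vs. Cilengitide. The first set alone gave 532 for SB273005 vs. PBS and, without SB273005 replicate 2, 423. The second set alone, where SB273005 replicate 4 is the only one of its group and is assumed to vary like the others, gave 32 for SB273005 vs. BAPN and 34 vs. Cilengitide. Unsplit BAPN libraries share noise, with opposite sign in the reversals and the same sign between inhibitors, and gave −0.0136 for the SB273005 reversal correlation and 0.548 between inhibitors. Of 93 list calls over the 6 comparisons, 2 held with an estimated correlation (neither without PBS replicate 3) and 21 with fry, which asks another question. The robust fit and DESeq2's size factors in edgeR left each of these within 1.5 times.

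The replicate block gave 141 genes for BAPN vs. PBS and 20 for SB273005 vs. BAPN and moved no other count by over 1.5 times. Whether the numbers pair the libraries is not settled, since the labels do not say what a shared number means. Over 19 same-numbered pairs the correlation of deviations averaged 0.123 (−0.159 to 0.337), against −0.043 over 54 other pairs. This difference was not tested.

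Leaving out 1 library at a time, the calls ranged from 2 to 186 for BAPN vs. PBS, 0 (edgeR) to 1 for Cilengitide vs. BAPN, 0 (edgeR) to 79 for SB273005 vs. BAPN, 0 (edgeR) to 15 for SB273005 vs. Cilengitide, 109 to 1249 for Cilengitide vs. PBS and 498 to 1988 for SB273005 vs. PBS. In BAPN vs. PBS they were 4, 2 and 4 without PBS replicates 1 to 3, 8, 4 and 6 without BAPN 1, 2 or 4, 13, 8 and 12 without Cilengitide 1 to 3, and 118, 186, 20 and 86 without SB273005 1 to 4. In SB273005 vs. BAPN they were 2, 0 and 1 without PBS 1 to 3, 47, 0, 0 and 2 without BAPN 1 to 4, 12, 0 and 1 without Cilengitide 1 to 3 and 0, 2 and 79 without SB273005 1, 2 or 4. For Cilengitide vs. PBS 435, 109 and 379 passed without PBS 1 to 3, 194 and 211 without Cilengitide 1 or 2 and 1249 without SB273005 2, and for SB273005 vs. PBS 1107, 498 and 932 without PBS 1 to 3. Without Cilengitide 2, 1 gene passed in Cilengitide vs. BAPN and 1 in SB273005 vs. Cilengitide, and without SB273005 4 15 passed in the latter. List calls ran from 85 to 101, the Cilengitide reversal from 0.234 to 0.354, that of SB273005 from 0.0528 to 0.207, and the correlation between inhibitors from 0.129 to 0.353, moving by more than its spread in 6 of 14 omissions.

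Over all settings, 23878 results of named genes held their side of the threshold, 1165 lost it, 332 gained it and 385 changed sign without being called in either fit. Those that held include genes that passed in neither fit, which is all of them in Cilengitide vs. BAPN and SB273005 vs. Cilengitide. They do not measure how far calls last: with 1 library left out, as few as 1 of the 31 calls in BAPN vs. PBS remained. At this depth and number of libraries, simulated genes changed 2-fold were recovered in 58.2% for Cilengitide vs. BAPN, 61.2% for SB273005 vs. BAPN and 53.7% for SB273005 vs. Cilengitide, and 1.5-fold in 11.9%, 19.4% and 10.4%. These simulations drew each gene independently with 200 genes changed, and 109, 122 and 105 genes passed, against 0, 4 and 0 in the data. The adjusted threshold is stricter where fewer genes pass, so these shares may be too high for the data.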

Other observations

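Genes named here outside the naming rule were chosen after their values were seen, as were the list tests with a library left out, and no explanation was tested for them. Cell cycle genes had a median of 1.13 in BAPN, 1.18 in Cilengitide and 1.34 in SB273005 vs. PBS (camera adjusted p = 1.5e-06, 6.61e-05 and 0.000623, adjusted p = 0.372, 0.563 and 0.673 with an estimated correlation). PBS replicate 1, the library with plasma cell transcripts, stood at 0.26 log2 units in this list, above BAPN replicates 2 to 4 (0.244, 0.092 and 0.0832), and PBS replicates 2 and 3 at −1.47 and −2. Without PBS replicate 1 the medians were 2.42, 2.27 and 2.51, and without replicate 3 that of BAPN was 0.75. SB273005 replicate 3 was at −0.775. Of 14 genes, 2 passed in SB273005 vs. PBS over all genes and 2 adjusted over the list alone: Cdk1, the mitotic kinase, rose by 2.30 ± 0.66 and Ccna2, cyclin A2, by 1.72 ± 0.51 (edgeR adjusted p = 0.0391 and 0.0417). Gpx3, a secreted glutathione peroxidase, was at 225 ± 27.6 FPKM in PBS, 469 ± 52.8 in BAPN, 538 ± 26.6 with Cilengitide and 381 ± 78.9 with SB273005, and rose vs. PBS in each (edgeR adjusted p = 0.0352, 0.00463 and 0.0109). For BAPN and Cilengitide the library set and the group cannot be told apart. Within the first set the rise of Gpx3 with SB273005 did not pass in edgeR. Klk10 was at 6.48, 2.70, 1.37 and 0.797 FPKM in PBS, BAPN, Cilengitide and SB273005, and fell vs. PBS by 2.21 and 2.97 with the inhibitors (edgeR adjusted p = 0.018 and 0.00243), while BAPN alone was at −1.26 ± 0.41 and did not pass (edgeR adjusted p = 0.2). The differences of either inhibitor from BAPN did not pass for Klk10 (edgeR adjusted p = 0.795 and 0.121). Mmp9, a gelatinase often measured in aneurysm, fell by 1.57 ± 0.35 in SB273005 vs. PBS, from 1.48 ± 0.206 to 0.468 ± 0.155 FPKM (edgeR adjusted p = 0.0132), while Mmp2 rose.

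Transcripts typical of other tissues were high in single libraries. PBS replicate 1 had 2640 FPKM of Igkc, the immunoglobulin κ constant gene, where the other PBS libraries had 11.4 and 9.60, and its B and plasma cell list stood at 5.42 log2 units. The same list had a median of −4.76 in BAPN vs. PBS (camera adjusted p = 0.00402, adjusted p = 0.426 with an estimated correlation), and one of 0.07 without that library (camera adjusted p = 0.657). Albumin, Alb, was at 123 and 68.4 FPKM in PBS replicates 1 and 2 and at 6.24 in replicate 3. Skeletal muscle actin, Acta1, was at 963 FPKM in PBS replicate 2 and 602 in BAPN replicate 3. Cthrc1 was at 92.5 FPKM in BAPN replicate 1 and at 4.27 to 4.55 in the other BAPN libraries. Hspa1b, an inducible heat shock gene, was at 613 FPKM in SB273005 replicate 4 and 19.2 to 165 in the others of its group.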
